A study of Mus musculus with 12 samples.

How the data were processed

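Gene expression of sorted mouse B lymphoma cells was measured on 12 Affymetrix whole-transcript mouse arrays, 3 in each of 4 groups. The deposited values are log2 expression signals, made with RMA and Affymetrix Power Tools per the submitters' processing notes. RMA corrects the background, normalizes the arrays to a common distribution and summarises the probes of a probe set, so small differences between dim probe sets are compressed toward background. Tool versions and the annotation behind the probe sets are not given in the sources used here. The values were used as deposited, with 0 columns of the table left without a sample. Array medians lay between 3.32 and 3.44 log2 units, 75th percentiles between 5.23 and 5.46 and maxima between 12.26 and 12.34. No detection calls were used, so a level near the array medians has no measured background beside it, and the number of arrays limits the precision.

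Of 35556 probe sets, 21218 had 1 gene symbol in the platform annotation used, 1881 had several and 12457 had none. Symbols of 21185 of the first kind were brought up to date by gene ID through a RefSeq gene table of assembly GRCm38.p6, used for names only, and 33 kept their original symbol. Probe sets with several genes or none were left out of the tests of genes. A probe set was kept when it exceeded its array's 40th percentile on at least 3 arrays, which left 23197 probe sets. Each gene was represented by its probe set with the highest mean, a choice that arose for 1037 of the 12961 genes tested.

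Groups were taken from the sample labels, and the tumour number in the sample titles was used as a block because each tumour occurs once in every group. The labels say that BCR-independent clones were mixed with BCR-positive cells of the same tumour. They leave open whether a tumour's BCR-positive and BCR-negative arrays came from 1 culture, how treated cultures were arranged, and what the (2) at the end of 4 titles (untreated BCR-positive and BCR-negative cells of tumours 2646 and 2676) marks. Treatment and culture coincide. Among arrays of like mark, treated and untreated BCR-negative cells can be paired in tumour 2567 alone, too few for a test. The residuals of arrays of the same tumour correlated between 0.2842 and 0.7919 and those of different tumours between -0.7159 and 0.165, and 12 of 12 arrays correlated best with an array of their own tumour. The first principal component held 35.9% of the variance, 89.2% of it between tumours. Each tumour gave 1 array per group, and p-values measure the spread between these samples. In R 4.3.3, limma 3.58.1 fitted group and tumour over all 12 arrays (lmFit and eBayes, 6 residual and 3.41 prior degrees of freedom), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All 6 pairs of groups were compared.

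Gene lists of pathways (24) and of markers of other cell types (5) were fixed in advance with 481 memberships, of which 368 were tested, and 28 lists had at least 3 tested members. Each was tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 28 lists of a comparison. Camera compares a list with other genes, and fry asks whether its genes move on balance one way. The genes named are the 10 with the largest increase and the 10 with the largest decrease among those called and changed alike in 3 tumours in the 3 main comparisons, the first 5 each way in the others, the 4 members with the smallest p of each list past camera, and fixed check genes. Predicted genes and small RNAs were counted and not named. Among the check genes, Ighd, Gsk3a and Trp53 had no single-gene probe set in the annotation used. These rules, the lists, the design and the alternatives were chosen before the data were examined. After their values were seen, named genes with a group mean below the median of every array and a dim array below its 40th percentile (Mgat4c, Tnf, Ciita and Myc) were set against that floor. The difference (for Mgat4c a lower limit, for Myc not printed) is the mean of the bright group minus the mean of, per dim array, the higher of its signal and that array's 40th percentile.

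The alternatives were no tumour block, no or a stricter filter (60th percentile), an intensity trend with robust eBayes, array weights, cyclic loess, quantile normalization, only the 2 groups compared, the mean of a gene's probe sets, a 1.5-fold threshold, an estimated correlation for the lists, and each tumour left out. The title mark as a term beside group and tumour (5 residual degrees of freedom) was added after the data were seen, for the numbers of genes and lists and for each named gene and list. Outside tumour 2567 the mark coincides with being untreated BCR-positive or BCR-negative. With it, comparisons of treated or BCR-independent cells with those groups rest in large part on tumour 2567. To test comparisons that share arrays, unchanged groups were simulated 100 times, with genes drawn independently, and covariances were also taken between different tumours. The fit was tested on simulated data for CHIR99021-treated against untreated BCR-negative cells, with 12961 genes, 200 of them changed, in 20 runs. It recovered 39.3% of changes of 0.5, 92.8% of changes of 1 and 99.2% of changes of 2 log2 units, with 4.73% of calls false. It made 1 call in the unchanged comparison of BCR-negative with BCR-positive cells over the 20 runs. A list shifted by 0.4 passed camera in 20 of 20 runs, and 0.15 of the other 27 lists passed per run. The runs drew every gene independently, so they do not test camera under the correlation between genes of real arrays. The shares recovered hold for 200 changed genes and can be lower where fewer change. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.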

Results

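Gene expression was measured in primary mouse B lymphoma cells that carry a MYC transgene and a B1-8 heavy chain gene that Cre recombinase can delete. The B cell receptor (BCR), the antigen receptor built around the immunoglobulin heavy chain, was removed with cell-permeable Cre, and cells with and without it were grown together and sorted after 4 days. The 12 arrays came from 3 tumours, numbered 2567, 2646 and 2676, each giving 1 array in each of 4 groups. These groups were untreated BCR-positive cells, untreated BCR-negative cells, BCR-negative cells exposed to CHIR99021 (an inhibitor of the kinase GSK3), and BCR-independent cells, which are BCR-negative clones obtained after long culture that were not outcompeted in a mixed culture. Values are deposited log2 signals of 35556 probe sets, with array medians between 3.32 and 3.44. The titles of the untreated BCR-positive and BCR-negative arrays of tumours 2646 and 2676 end in (2), a mark that the labels do not explain, and the other 8 arrays carry none. After removal of dim probe sets, 12961 genes were tested. All changes are on the log2 scale, with n = 3 arrays per group, and the number of arrays limits their precision. Parentheses after a list give the settings that ended its call, and a list's median without a tumour (by number) or under another setting where that moved by over 1.5 times or in sign. The mark there stands for the title mark as a term, and turned for a change of camera's direction. Named list members have their value without a tumour by the same rule. Of the 60 calls of named genes, 0 moved so far without a tumour, and with the mark only those of Ccng2 and Slc7a5 did.

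The comparison of BCR-negative with BCR-positive cells sorted from mixed cultures addresses what loss of the receptor changes. Ighv1-72, the variable segment of the B1-8 heavy chain, checks the sort labels and fell from 9.62 ± 0.30 in BCR-positive cells to 6.44 ± 0.57 in BCR-negative cells (SD, n = 3). That change of -3.18 (SE 0.31, adjusted p = 0.0241) was seen in each of the 3 tumours, at -2.48, -3.60 and -3.47. Ighv1-72 read 5.77 ± 0.73 in treated BCR-negative cells and 4.04 ± 0.28 in BCR-independent cells. Heavy chain variable segments include near-identical copies, so the share of this signal that belongs to Ighv1-72 itself is uncertain. The Ighm probe set read 4.09 in BCR-positive and 3.76 in untreated BCR-negative cells, near the array medians, and checks nothing here. Which part of the transcript it reads was not examined. Ighv1-72 was the 1 gene of 12961 called by limma, and 413 genes had an unadjusted p under 0.05, where 648.1 are expected by chance. Without the tumour block 0 genes were called, and leaving out tumour 2567, 2646 or 2676 left 0, 0 and 0 calls, and with the title mark as a term 2 genes were called.

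**Figure D1:**
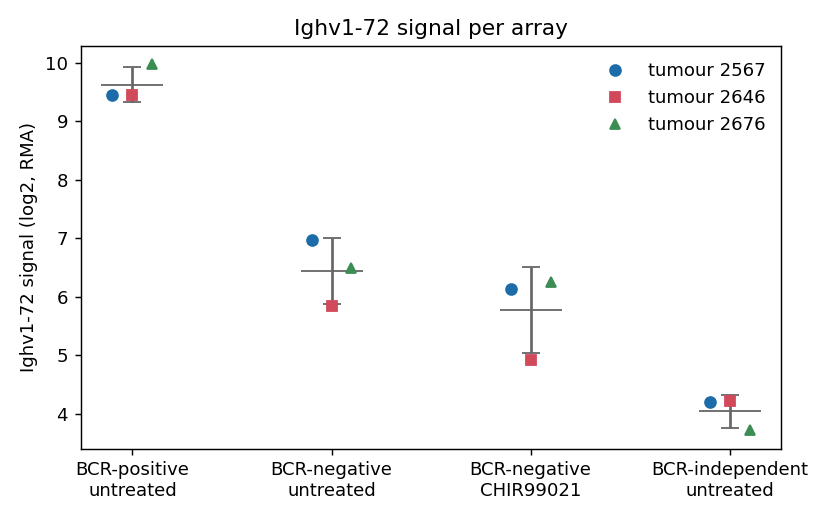
Ighv1-72 signal (log2, y axis) on each of the 12 arrays, by group (x axis). Symbols are tumours and grey bars are the mean ± SD of 3 arrays. BCR-positive arrays averaged 9.62, untreated BCR-negative arrays 6.44, treated BCR-negative arrays 5.77 and BCR-independent arrays 4.04.

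Among 28 gene lists tested, 8 passed camera's preset test at BCR loss, 2 upward and 6 downward, and 0 held with an estimated correlation or passed fry. The MHC class II and costimulation genes fell (camera adjusted p = 0.00016, and adjusted p = 0.652 with an estimated correlation). 6 of 8 members were lower, with a median change of -0.64 (-1.0 and -0.30 without 2646 and 2676, -0.30 with no filter, -1.06 with the stricter filter). Cd74 (-2.09), Ciita (-0.48), H2-Eb1 (-1.30, -0.65 without 2676) and H2-Aa (-1.76, -1.03 without 2676) led the list by p, and 0 members passed over all genes and 4 adjusted over the list alone. Cd74, the invariant chain of MHC class II, changed by -2.18, -1.91 and -2.17 in the 3 tumours. The FOXO target genes rose (camera adjusted p = 0.000351, lost without 2646, and adjusted p = 0.491 with an estimated correlation). 14 of 16 members were higher, with a median change of 0.29 (0.13 without 2646). Irs2 (0.48, 0.11 without 2676), Rag2 (1.11, 0.34 without 2646), Insr (0.36, 0.22 without 2567) and S1pr1 (0.59, 0.95 and 0.30 without 2567 and 2646) led the list by p. The NF-kB target genes rose (camera adjusted p = 0.00276, lost without 2646 and with the stricter filter, and adjusted p = 0.491 with an estimated correlation). 13 of 16 members were higher, with a median change of 0.12 (0.044 and 0.18 without 2646 and 2676). Cd40 (0.31, 0.15 and 0.48 without 2646 and 2676), Nfkb2 (0.29), Tnf (0.41, 0.37 with the 40th percentile as floor, 0.68 and 0.0654 without 2567 and 2646) and Bcl3 (0.16, 0.10 and 0.23 without 2567 and 2646) led the list by p. Group means of these 4 lay between 3.08 and 3.79, near the array medians, and Tnf exceeded the 40th percentile on 1 of 3 BCR-positive arrays. Unfolded protein response genes fell (camera adjusted p = 9.71e-05, lost without 2646, and adjusted p = 0.491 with an estimated correlation). 15 of 17 members were lower, with a median change of -0.18 (-0.29 and -0.0602 without 2567 and 2646). Syvn1 (-0.26), Manf (-0.29), Sel1l (-0.26) and Hspa5 (-0.24, -0.41 and -0.10 without 2567 and 2646) led the list by p. DNA replication genes fell (camera adjusted p = 9.71e-05, lost without 2676, and adjusted p = 0.726 with an estimated correlation). 18 of 20 members were lower, with a median change of -0.13 (-0.25, -0.0724 and -0.0764 without 2567, 2646 and 2676). Rrm2 (-0.40), Uhrf1 (-0.33), Mcm3 (-0.24, -0.15 without 2676) and Mcm4 (-0.21) led the list by p. MYC target and ribosome biogenesis genes fell (camera adjusted p = 0.00276, lost without 2646 and 2676, and adjusted p = 0.756 with an estimated correlation). 23 of 25 members were lower, with a median change of -0.0697 (-0.16 and 0.0122 without 2567 and 2646, -0.11 with array weights). Tfrc (-0.50, -0.28 without 2646), Odc1 (-0.27, -0.11 without 2646), Tcof1 (-0.19, -0.11 without 2676) and Polr1b (-0.18, -0.29 and -0.00099 without 2567 and 2646) led the list by p. Nucleotide and one-carbon synthesis genes fell (camera adjusted p = 0.0222, lost without 2646 and 2676, without the tumour block, after quantile normalization and with mean probe sets, and adjusted p = 0.747 with an estimated correlation). 16 of 18 members were lower, with a median change of -0.10 (-0.20, -0.0283 and -0.0591 without 2567, 2646 and 2676). Prps1 (-0.17, -0.26 and -0.0637 without 2567 and 2676), Ppat (-0.20, -0.32 and -0.00688 without 2567 and 2646), Mthfd1l (-0.17, -0.34, -0.11 and -0.0562 without 2567, 2646 and 2676) and Atic (-0.11, -0.19 and -0.0558 without 2567 and 2676) led the list by p. The TCA cycle and respiratory chain genes fell (camera adjusted p = 0.0222, lost without 2646 and 2676, and adjusted p = 0.726 with an estimated correlation). 14 of 18 members were lower, with a median change of -0.076 (-0.0295 without 2646). Ogdh (-0.23), Cycs (-0.22, -0.34 and -0.13 without 2567 and 2646), Dlst (-0.14, -0.22 and -0.0722 without 2567 and 2676) and Ndufs1 (-0.15, -0.29 and -0.0242 without 2567 and 2646) led the list by p. At BCR loss, 0 members of the lists given with no such count passed over all genes or adjusted over the list alone. At BCR loss, tumour 2567 had medians opposite to the fitted ones, at -0.00209 for FOXO target genes, 0.10 for unfolded protein response genes, 0.0802 for DNA replication genes, 0.0863 for MYC target and ribosome biogenesis genes, 0.11 for nucleotide and one-carbon synthesis genes and 0.00379 for TCA cycle and respiratory chain genes. Without tumour 2567, 2646 or 2676, 8, 3 and 4 lists passed. In 5 of the 6 comparisons another split of the same 6 arrays gave more lists than the real one, which limits every list call given here.

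BCR-independent clones were compared with BCR-negative cells of the same tumours, which asks what sets clones that persist without the receptor apart. Mgat4c, of a family of N-acetylglucosaminyltransferases that branch N-glycans, rose from 3.23 ± 0.45 to 6.39 ± 0.30 (SD, n = 3), a change of 3.16 (SE 0.27, adjusted p = 0.00808) seen in all 3 tumours. The level in BCR-negative cells lay below the array medians, with 2 of 3 arrays above their 40th percentile, and with that percentile as a floor the change was at least 3.07. Mgat4c was the 1 gene called by limma, with 776 genes at an unadjusted p under 0.05 and 648.1 expected. Ighv1-72 differed by -2.40 (adjusted p = 0.135) and missed the threshold. Without the tumour block 0 genes were called, as with only the 2 groups in the fit (0), and leaving out tumour 2567, 2646 or 2676 gave 0, 3 and 0 calls, and with the title mark as a term 0 genes were called.

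By camera's preset test 9 of the 28 lists passed between BCR-independent and BCR-negative cells, 4 upward and 5 downward, and 0 held with an estimated correlation or passed fry. The MYC target and ribosome biogenesis genes rose (camera adjusted p = 4.37e-05, lost without 2676, turned and lost with the mark, and adjusted p = 0.714 with an estimated correlation). 23 of 25 members were higher, with a median change of 0.21 (0.11 without 2676, 0.0339 with the mark). Pprc1 (0.45), Nop56 (0.24), Nolc1 (0.33, 0.17 without 2676) and Wdr43 (0.29, 0.44 without 2567) led the list by p. The nucleotide and one-carbon synthesis genes rose (camera adjusted p = 0.00976, lost without 2646 and 2676, without the tumour block and with the mark, and adjusted p = 0.714 with an estimated correlation). 14 of 18 members were higher, with a median change of 0.14 (0.25, 0.0771 and 0.0419 without 2567, 2646 and 2676, 0.0394 with the mark). Gart (0.28), Shmt2 (0.42), Atic (0.23) and Cad (0.27, 0.40 and 0.0895 without 2567 and 2676) led the list by p. The cholesterol synthesis genes rose (camera adjusted p = 0.00539, lost without 2646, turned and lost with the mark, and adjusted p = 0.714 with an estimated correlation). 20 of 20 members were higher, with a median change of 0.21 (0.045 without 2646, -0.0535 with the mark). Dhcr7 (0.25), Mvk (0.21), Pmvk (0.32, 0.15 without 2646) and Sqle (0.21) led the list by p. The unfolded protein response genes rose (camera adjusted p = 0.00539, lost without 2676 and with the mark, and adjusted p = 0.714 with an estimated correlation). 15 of 17 members were higher, with a median change of 0.11 (0.17 and 0.19 without 2567 and 2646, 0.33 with the mark). Manf (0.32, 0.21 without 2567), Dnajb11 (0.34), Pdia6 (0.45, 0.28 without 2676) and Hspa5 (0.25) led the list by p. The hypoxia response genes fell (camera adjusted p = 0.000500, lost without 2646 and 2676, turned and lost with the mark, and adjusted p = 0.714 with an estimated correlation). 13 of 15 members were lower, with a median change of -0.29 (-0.61, -0.0935 and -0.11 without 2567, 2646 and 2676, 0.27 with the mark). Kdm3a (-0.88, -0.58 without 2676), Adm (-0.64, -0.97 and -0.31 without 2567 and 2676), Vegfa (-0.51) and Ankrd37 (-1.36, -2.49, -0.88 and -0.73 without 2567, 2646 and 2676) led the list by p. The early B cell and recombination genes fell (camera adjusted p = 0.0021, lost without 2676, and adjusted p = 0.714 with an estimated correlation). 7 of 9 members were lower, with a median change of -0.56 (-0.073 without 2676, -0.24 with no filter). Myb (-0.56), Il7r (-1.60, -0.81 without 2567), Sox4 (-1.24, -0.49 without 2567) and Igll1 (-1.67, -0.53 without 2676) led the list by p, and 0 members passed over all genes and 2 adjusted over the list alone. The FOXO target genes fell (camera adjusted p = 0.00531, lost without 2646 and 2676 and with the mark, and adjusted p = 0.714 with an estimated correlation). 15 of 16 members were lower, with a median change of -0.21 (-0.39, -0.14 and -0.0478 without 2567, 2646 and 2676, -0.088 with the mark). Il7r (-1.60, -0.81 without 2567), Ccng2 (-0.87, -0.51 without 2676), Cdkn1b (-0.54, -0.91 and -0.16 without 2567 and 2676) and Sesn3 (-0.30, -0.50 and -0.13 without 2567 and 2646) led the list by p. The mitosis genes fell (camera adjusted p = 0.00646, lost without 2646 and 2676, turned and lost with the mark, and adjusted p = 0.714 with an estimated correlation). 14 of 16 members were lower, with a median change of -0.10 (-0.22 and -0.00796 without 2567 and 2676, 0.14 with the mark). Mki67 (-0.26, -0.46, -0.16 and -0.15 without 2567, 2646 and 2676), Cenpe (-0.42, -0.20 without 2646), Bub1b (-0.21, -0.0628 without 2676) and Ccna2 (-0.19, -0.0865 without 2646) led the list by p. The p53 target genes fell (camera adjusted p = 0.0396, lost without each tumour, without the tumour block, with no filter, with the stricter filter, after quantile normalization, with only the 2 groups and with the mark, and adjusted p = 0.714 with an estimated correlation). 9 of 14 members were lower, with a median change of -0.0668 (-0.13 and -0.15 without 2567 and 2676, -0.0137 with no filter, -0.0275 with the stricter filter). Mdm2 (-0.36), Plk2 (-1.39, -0.78 and -2.21 without 2567 and 2646), Trp53inp1 (-0.46, -0.80 and -0.17 without 2567 and 2676) and Sesn2 (0.29, 0.19 without 2676) led the list by p. In BCR-independent cells, 0 members of the lists given with no such count passed over all genes or adjusted over the list alone. In BCR-independent cells, tumour 2567 had medians opposite to the fitted ones, at -0.057 for MYC target and ribosome biogenesis genes, -0.12 for nucleotide and one-carbon synthesis genes, 0.26 for hypoxia response genes, 0.20 for FOXO target genes, 0.0912 for mitosis genes and 0.00674 for p53 target genes. With tumour 2567, 2646 or 2676 left out, 13, 4 and 1 lists passed, and with the title mark as a term 3, 1 of them among the 9.

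Treated and untreated BCR-negative cells were compared to ask what GSK3 inhibition changes in cells without the receptor. Treatment and culture coincide in this comparison. Limma called 248 genes, 138 higher and 110 lower in treated cells, all in the same direction in the 3 tumours, and 47 of them by at least 2-fold. With the title mark as a term 32 genes were called, 14 of them among the 248. The median SE then rose from 0.117 to 0.155. Klhl24 fell by 2.90 on the log2 scale, from 7.81 ± 0.39 to 4.91 ± 0.52 (SD, n = 3). Trp53inp1, a stress-induced protein, changed by -2.68 (SE 0.26, adjusted p = 0.00439) and Mxd4, which pairs with MAX in competition with MYC, by -2.04 (SE 0.20, adjusted p = 0.00439). Ccng2 (cyclin G2, a FOXO target) changed by -2.01 (SE 0.32, adjusted p = 0.0278, -1.22 with the mark), the histone variant H2az2 by -1.95 and Pdcd4, an inhibitor of translation, by -1.67. The other large decreases were Tifa (-1.94), Akap12 (-1.75), Fbxl20 (-1.51) and Pafah1b3 (-1.42). Among the increases, the fatty acid receptor Cd36 changed by 2.74 (SE 0.45, adjusted p = 0.0304), Pld4 by 2.35 (SE 0.45, adjusted p = 0.0405) and Tlr9, a sensor of unmethylated DNA, by 1.14 (SE 0.16, adjusted p = 0.0226). Further increases were Reep6 (1.64), Tspan4 (1.16), Frrs1 (1.12), Zfp385a (1.12), Slc25a12 (1.11), Ppp2r5b (1.09) and Car12 (1.05), where Slc25a12 is the mitochondrial aspartate and glutamate carrier.

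At an unadjusted p under 0.05, 2147 genes differed under CHIR99021, against 648.1 expected. The count rested on the tumour block and on all 3 tumours, with 12 genes called without the block, and 17, 1 and 10 without tumour 2567, 2646 or 2676. It was 109 (32 higher, 77 lower) with only the 2 groups in the fit and 1635 with array weights, and the 138 higher and 110 lower turned to 107 and 115 after quantile normalization and to 104 and 132 after cyclic loess.

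**Figure D2:**
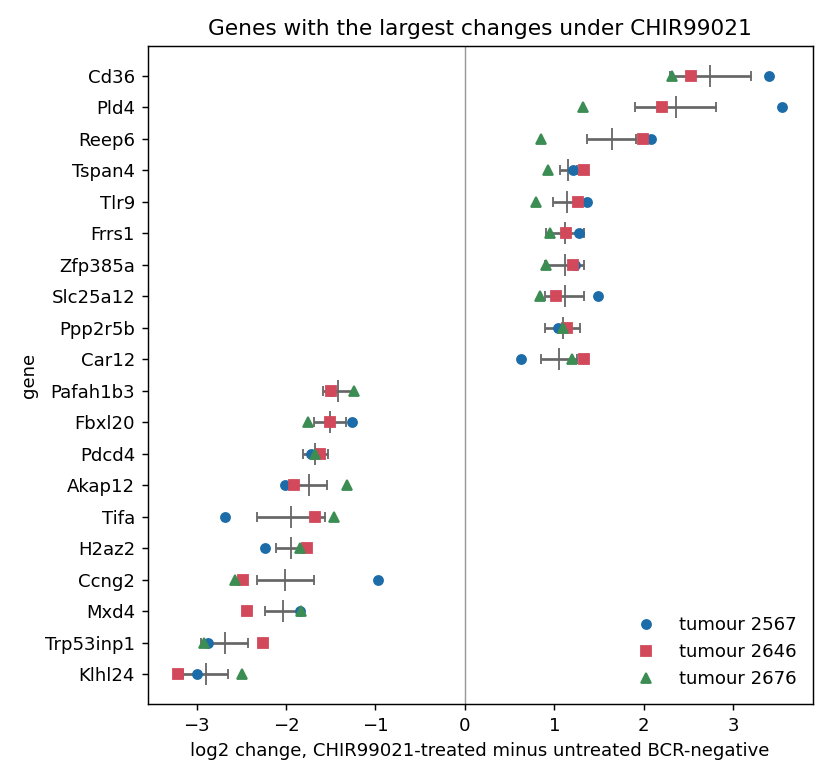
Change under CHIR99021 (log2, x axis) of the 10 genes that increased and the 10 that decreased most among those called (y axis). Symbols are the 3 tumours, and grey bars are the fitted change ± SE. Each gene lies on the same side of 0 in all 3 tumours, from Cd36 at 2.74 to Klhl24 at -2.90.

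Under CHIR99021 10 of the 28 lists passed camera's preset test, 5 upward and 5 downward, 0 held with an estimated correlation, and 5 passed fry. With the title mark as a term 10 passed, 6 of them among these. The MYC target and ribosome biogenesis genes rose (camera adjusted p = 1.60e-12, and adjusted p = 0.388 with an estimated correlation). 25 of 25 members were higher, with a median change of 0.44 (0.27 with the mark). Rrp12 (0.61), Phb (0.44), Tcof1 (0.51) and Nop16 (0.45) led the list by p, and 0 members passed over all genes and 19 adjusted over the list alone. The ATF4 and amino acid response genes rose (camera adjusted p = 1.96e-05, lost with the mark, and adjusted p = 0.388 with an estimated correlation). 16 of 18 members were higher, with a median change of 0.48 (0.28 without 2646, 0.30 with the mark). Slc3a2 (0.74), Psph (0.68), Nars (0.64) and Slc7a5 (0.95, 0.48 with the mark) led the list by p, and 4 members passed over all genes and 13 adjusted over the list alone (11 higher and 2 lower). Slc3a2 and Slc7a5 form an amino acid transporter. The nucleotide and one-carbon synthesis genes rose (camera adjusted p = 1.22e-07, and adjusted p = 0.388 with an estimated correlation). 18 of 18 members were higher, with a median change of 0.30. Gart (0.54), Adsl (0.46), Atic (0.36) and Shmt2 (0.52) led the list by p, and 1 member passed over all genes and 4 adjusted over the list alone. The TCA cycle and respiratory chain genes rose (camera adjusted p = 8.54e-05, and adjusted p = 0.388 with an estimated correlation). 16 of 18 members were higher, with a median change of 0.22. Idh3a (0.64), Cs (0.45), Cycs (0.34) and Suclg1 (0.28) led the list by p, and 1 member passed over all genes and 2 adjusted over the list alone. The unfolded protein response genes rose (camera adjusted p = 0.0252, lost without 2676, with the stricter filter and with the mark, and adjusted p = 0.61 with an estimated correlation). 13 of 17 members were higher, with a median change of 0.29. Canx (0.34), Manf (0.39), Calr (0.39) and Dnajb11 (0.42) led the list by p, and 0 members passed over all genes and 5 adjusted over the list alone. The FOXO target genes fell (camera adjusted p = 2.22e-08, and adjusted p = 0.25 with an estimated correlation). 15 of 16 members were lower, with a median change of -0.68. Ccng2 (-2.01, -1.22 with the mark), Cdkn1b (-1.15), Rag2 (-2.03) and Gadd45a (-0.89) led the list by p, and 1 member passed over all genes and 8 adjusted over the list alone. These were the lists that passed fry apart from the unfolded protein response, at adjusted p = 0.0383 for the ATF4 list and adjusted p = 0.0311 for the other 4. The early B cell and recombination genes fell (camera adjusted p = 0.00122, and adjusted p = 0.39 with an estimated correlation). 7 of 9 members were lower, with a median change of -0.83 (-0.11 with no filter). Myb (-0.83), Rag2 (-2.03), Cd93 (-1.18) and Sox4 (-1.49) led the list by p, and 1 member passed over all genes and 4 adjusted over the list alone. The mature follicular B cell genes fell (camera adjusted p = 0.0174, and adjusted p = 0.39 with an estimated correlation). 6 of 8 members were lower, with a median change of -0.37 (-0.23 without 2646, -0.13 with no filter, -0.12 with the mark). Ebf1 (-1.21), Pax5 (-0.46), Ccr7 (-0.88, -0.59 without 2567) and Cd22 (-0.37) led the list by p, and 0 members passed over all genes and 3 adjusted over the list alone. The hypoxia response genes fell (camera adjusted p = 0.00341, lost without 2676, turned and lost with the mark, and adjusted p = 0.625 with an estimated correlation). 11 of 15 members were lower, with a median change of -0.37 (-0.73, -0.17 and -0.24 without 2567, 2646 and 2676, 0.31 with the mark). Kdm3a (-1.26), Mxi1 (-0.63), Ndrg1 (-0.87) and Adm (-0.56, -0.87 and -0.24 without 2567 and 2676) led the list by p, and 0 members passed over all genes and 2 adjusted over the list alone. The mitosis genes fell (camera adjusted p = 0.000481, lost without 2676 and with the mark, and adjusted p = 0.625 with an estimated correlation). 13 of 16 members were lower, with a median change of -0.20 (-0.11 without 2676, 0.00526 with the mark). Mki67 (-0.50), Cenpf (-0.65), Kif11 (-0.35, -0.22 without 2676) and Top2a (-0.31) led the list by p. Under CHIR99021, 0 members of the mitosis genes passed over all genes or adjusted over the list alone. Under CHIR99021, tumour 2567 had medians opposite to the fitted ones, at 0.28 for hypoxia response genes.

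**Figure D3:**
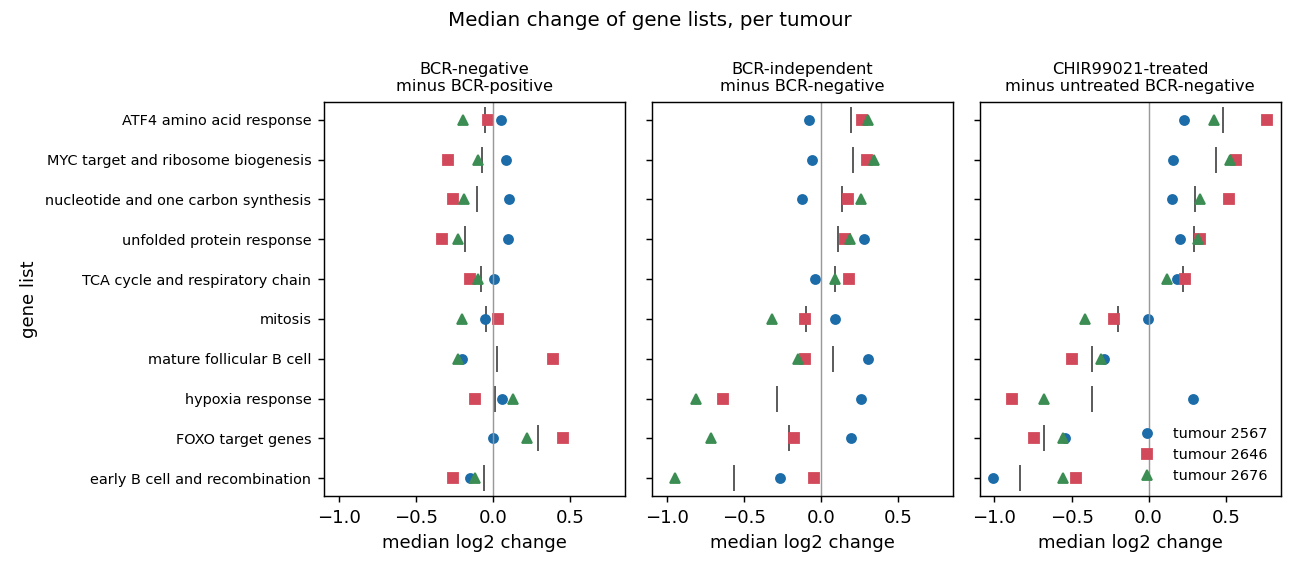
Median log2 change (x axis) of the 10 gene lists that passed camera under CHIR99021 (y axis), in 3 comparisons. Symbols are the medians in each tumour and the grey tick is the median of the fitted changes. MYC target genes had a median of -0.07 at BCR loss, 0.21 in BCR-independent cells and 0.44 under CHIR99021, and FOXO target genes 0.29, -0.21 and -0.68.

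BCR-independent and BCR-positive cells were compared to describe the whole distance between the clones and cells that keep the receptor. Ighv1-72 changed by -5.58 (SE 0.31, adjusted p = 0.000156) and Cd74 by -3.52 (SE 0.35, adjusted p = 0.00938), from 8.46 ± 0.94 to 4.93 ± 0.24 (SD, n = 3). The other named decreases were Prkca (-1.29), Xylt1 (-1.04) and Galnt14 (-0.95), with Prkca encoding a protein kinase C. Increases were Mgat4c (3.17), Lhx2 (1.60), Atp6v0a1 (1.43), Dstn (1.17) and Dennd1a (1.11), where Lhx2 is a homeobox transcription factor and Atp6v0a1 a subunit of the vacuolar proton pump. Mgat4c exceeded the 40th percentile on 1 of 3 BCR-positive arrays, which with that floor makes its change at least 2.94. These belong to the 11 genes called by limma, 5 higher and 6 lower, all the same way in 3 tumours. The count was 4 without the tumour block, 1 with only the 2 groups, 3 with array weights, 12 with the title mark as a term (4 of them among the 11), and 4, 4 and 1 without tumour 2567, 2646 or 2676. 5 lists passed camera downward, 0 held with an estimated correlation and 0 passed fry. The MHC class II and costimulation genes fell (camera adjusted p = 0.00275, lost without 2646 and 2676 and with the mark, and adjusted p = 0.932 with an estimated correlation). 5 of 8 members were lower, with a median change of -1.04 (-0.34 without 2676, -0.38 with no filter, -0.18 with the mark). Cd74 (-3.52), H2-Aa (-2.76, -1.65 without 2676), Ciita (-0.66, 0.66 in size with the 40th percentile as floor) and H2-Eb1 (-1.42, -0.73 without 2676) led the list by p, and 1 member passed over all genes and 4 adjusted over the list alone. Early B cell and recombination genes fell (camera adjusted p = 0.00275, lost without 2567 and without the tumour block, and adjusted p = 0.932 with an estimated correlation). 5 of 9 members were lower, with a median change of -0.74 (-0.44 without 2676, -0.0021 with no filter, -1.16 with the stricter filter). Myb (-0.74), Il7r (-1.90, -1.22 without 2567), Igll1 (-2.60, -1.45 without 2676) and Vpreb1 (-1.25, -0.44 without 2676) led the list by p, and 0 members passed over all genes and 4 adjusted over the list alone. In BCR-independent against BCR-positive cells, DNA replication genes fell (camera adjusted p = 3.13e-06, and adjusted p = 0.932 with an estimated correlation). 19 of 20 members were lower, with a median change of -0.23 (-0.12 without 2676). Uhrf1 (-0.41), Mcm4 (-0.34), E2f1 (-0.39, -0.17 without 2646) and Cdc45 (-0.36, -0.19 without 2676) led the list by p. Hypoxia response genes fell (camera adjusted p = 0.00275, lost without 2646 and 2676, turned and lost with the mark, and adjusted p = 0.932 with an estimated correlation). 12 of 15 members were lower, with a median change of -0.20 (-0.56, -0.0318 and -0.11 without 2567, 2646 and 2676, 0.24 with the mark). Vegfa (-0.77), Kdm3a (-0.91, -1.38 and -0.60 without 2567 and 2676), Adm (-0.74) and Ankrd37 (-1.52, -2.68 and -0.84 without 2567 and 2646) led the list by p, and 0 members passed over all genes and 3 adjusted over the list alone. Mitosis genes fell (camera adjusted p = 0.000735, lost without 2676, turned and lost with the mark, and adjusted p = 0.932 with an estimated correlation). 15 of 16 members were lower, with a median change of -0.20 (-0.34 and -0.0466 without 2567 and 2676, 0.0605 with the mark). Mki67 (-0.30, -0.45 and -0.19 without 2567 and 2676), Kif11 (-0.28, -0.0933 without 2676), Aurka (-0.31, -0.19 without 2676) and Bub1b (-0.26, -0.40 and -0.0324 without 2567 and 2676) led the list by p. Against BCR-positive cells, 0 members of the lists given with no such count passed over all genes or adjusted over the list alone. Against BCR-positive cells, tumour 2567 had medians opposite to the fitted ones, at 0.30 for hypoxia response genes and 0.11 for mitosis genes. Without those tumours in turn 7, 3 and 5 lists passed, and with the title mark as a term 3, 2 of them among the 5.

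Treated BCR-negative cells were compared with untreated BCR-positive cells to see how far the treated cells lie from cells that keep the receptor. Limma called 104 genes, 46 higher and 58 lower. Ighv1-72 changed by -3.85 (SE 0.31, adjusted p = 0.00349), followed by Klhl24 (-2.63), Trp53inp1 (-2.18), Ccng2 (-1.89, -1.10 with the mark) and H2az2 (-1.80). Increases were Reep6 (1.52), Lmo2 (1.38), Car12 (1.17), Lrp8 (1.06) and Tspan4 (1.05), where Lmo2 is a transcriptional cofactor and Lrp8 a lipoprotein receptor. Of the genes called under CHIR99021 against BCR-negative cells, 35 of the higher and 48 of the lower were called here too. Both comparisons share the treated arrays, and equally long lists overlapped by 13.8 ± 2.82 and 14.8 ± 3.15 genes (SD) in 100 simulations of unchanged groups. These simulations treat genes as independent, so their SD leaves out correlation between genes. Independent lists would overlap by 0.49 and 0.492. The count was 7 without the tumour block, 0 with only the 2 groups, 168 with array weights, 8 with the title mark as a term and 183 (59 higher, 124 lower) after cyclic loess. It was 19, 4 and 15 without tumour 2567, 2646 or 2676.

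Camera passed 12 lists between treated BCR-negative and BCR-positive cells, 4 upward and 8 downward, with 0 holding under an estimated correlation and 0 passing fry. MYC target and ribosome biogenesis genes rose (camera adjusted p = 3.60e-08, lost with the mark, and adjusted p = 0.448 with an estimated correlation). 24 of 25 members were higher, with a median change of 0.32 (0.14 with the mark). Phb (0.38), Nop16 (0.41), Pa2g4 (0.27) and Rrp12 (0.44) led the list by p, and 0 members passed over all genes and 11 adjusted over the list alone. Nucleotide and one-carbon synthesis genes rose (camera adjusted p = 0.000138, lost with the mark, and adjusted p = 0.448 with an estimated correlation). 18 of 18 members were higher, with a median change of 0.24. Gart (0.48), Adsl (0.42), Dhodh (0.32) and Atic (0.25) led the list by p, and 0 members passed over all genes and 2 adjusted over the list alone. ATF4 and amino acid response genes rose (camera adjusted p = 0.000164, lost with the mark, and adjusted p = 0.448 with an estimated correlation). 16 of 18 members were higher, with a median change of 0.35. Slc3a2 (0.64), Slc7a5 (0.90), Nars (0.56) and Phgdh (0.39) led the list by p, and 1 member passed over all genes and 11 adjusted over the list alone (9 higher and 2 lower). TCA cycle and respiratory chain genes rose (camera adjusted p = 0.0113, lost without 2567 and with the mark, and adjusted p = 0.486 with an estimated correlation). 15 of 18 members were higher, with a median change of 0.12. Idh3a (0.52), Suclg1 (0.32), Cs (0.37) and Mdh2 (0.21) led the list by p, and 0 members passed over all genes and 3 adjusted over the list alone. Early B cell and recombination genes fell (camera adjusted p = 0.000164, and adjusted p = 0.448 with an estimated correlation). 9 of 9 members were lower, with a median change of -0.91. Myb (-1.01), Sox4 (-1.41, -0.81 without 2646), Cd93 (-0.97, -0.52 and -1.65 without 2567 and 2646) and Il7r (-1.18) led the list by p, and 1 member passed over all genes and 1 adjusted over the list alone. FOXO target genes fell (camera adjusted p = 0.000502, and adjusted p = 0.448 with an estimated correlation). 12 of 16 members were lower, with a median change of -0.37 (-0.24 with the mark). Ccng2 (-1.89, -1.10 with the mark), Cdkn1b (-1.01), Ccr7 (-0.75) and Il7r (-1.18) led the list by p, and 1 member passed over all genes and 2 adjusted over the list alone. Mature follicular B cell genes fell (camera adjusted p = 0.00764, lost without 2567, and adjusted p = 0.448 with an estimated correlation). 6 of 8 members were lower, with a median change of -0.39 (-0.21 with no filter). Ebf1 (-1.26), Pax5 (-0.50), Ccr7 (-0.75) and Spib (-0.54, -0.82 and -0.28 without 2567 and 2646) led the list by p, and 0 members passed over all genes and 2 adjusted over the list alone. BCR complex and proximal signalling genes fell (camera adjusted p = 0.0143, lost without 2676 and with the mark, and adjusted p = 0.486 with an estimated correlation). 9 of 16 members were lower, with a median change of -0.25 (-0.11 without 2676, -0.0416 with the mark). Cd72 (-0.95, -0.63 without 2676), Fcgr2b (0.83), Blk (-1.60, -0.92 without 2676) and Syk (-0.54) led the list by p, and 0 members passed over all genes and 6 adjusted over the list alone (1 higher and 5 lower). MHC class II and costimulation genes fell (camera adjusted p = 0.0138, lost without 2676, turned and lost with the mark, and adjusted p = 0.555 with an estimated correlation). 7 of 8 members were lower, with a median change of -0.42 (-0.75, -0.78 and -0.0931 without 2567, 2646 and 2676, -0.24 with no filter, -0.74 with the stricter filter, 0.21 with the mark). Cd74 (-1.06), H2-Aa (-1.48, -0.76 without 2676), H2-Eb1 (-0.93, -1.53 and -0.28 without 2567 and 2676) and Ciita (-0.30, -0.54 and -0.16 without 2567 and 2676) led the list by p. Hypoxia response genes fell (camera adjusted p = 0.00256, lost without 2646, turned and lost with the mark, and adjusted p = 0.555 with an estimated correlation). 12 of 15 members were lower, with a median change of -0.27 (-0.72 and -0.00675 without 2567 and 2646, -0.49 with the stricter filter, 0.23 with the mark). Kdm3a (-1.30), Mxi1 (-0.62, -0.38 without 2646), Adm (-0.66) and Ndrg1 (-0.81, -0.52 without 2676) led the list by p, and 0 members passed over all genes and 2 adjusted over the list alone. Mitosis genes fell (camera adjusted p = 1.15e-05, lost without 2676 and with the mark, and adjusted p = 0.486 with an estimated correlation). 15 of 16 members were lower, with a median change of -0.25 (-0.39 and -0.0744 without 2567 and 2676, 0.0144 with the mark). Mki67 (-0.55), Top2a (-0.50), Kif11 (-0.45, -0.24 without 2676) and Cenpf (-0.60, -0.95 and -0.40 without 2567 and 2646) led the list by p, and 0 members passed over all genes and 3 adjusted over the list alone. DNA replication genes fell (camera adjusted p = 0.000349, lost without 2676, and adjusted p = 0.555 with an estimated correlation). 18 of 20 members were lower, with a median change of -0.13 (-0.20 and -0.0324 without 2646 and 2676, -0.22 with the mark). Ccne1 (0.46), Uhrf1 (-0.40), Mcm7 (-0.39) and Mcm4 (-0.33) led the list by p, and 0 members passed over all genes and 3 adjusted over the list alone (1 higher and 2 lower). In treated cells, 0 members of the MHC class II and costimulation genes passed over all genes or adjusted over the list alone. In treated cells, tumour 2567 had medians opposite to the fitted ones, at 0.0204 for BCR complex and proximal signalling genes, 0.10 for MHC class II and costimulation genes, 0.28 for hypoxia response genes and 0.0651 for mitosis genes. The number of lists was 11, 12 and 8 without tumour 2567, 2646 or 2676, and 6 with the title mark as a term, 4 of them among the 12.

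Treated BCR-negative cells and BCR-independent clones, the groups reached by GSK3 inhibition and by long culture, were compared directly. Limma called 21 genes, 4 higher and 17 lower in treated cells. Cd74 was higher by 2.46 (SE 0.35, adjusted p = 0.0383), and Kcnab2 (0.81), Tspan4 (0.75) and Prdx3 (0.58) were higher too, Prdx3 being a mitochondrial peroxiredoxin. Mgat4c, above the 40th percentile on 0 of 3 treated arrays, was higher in the clones by at least 3.29 with that floor (fitted change -3.52, adjusted p = 0.00311), and Klhl24 (-2.39), Trp53inp1 (-2.22), Mxd4 (-1.56) and H2az2 (-1.56) were lower in treated cells. The count was 5 without the tumour block, 1 with only the 2 groups, 39 with array weights, 33 with the title mark as a term, 37 after cyclic loess and 33 after quantile normalization. It was 0, 2 and 12 without tumour 2567, 2646 or 2676. 7 lists passed camera, 4 higher and 3 lower in treated cells, 0 held with an estimated correlation and 0 passed fry. In treated cells, MYC target and ribosome biogenesis genes rose (camera adjusted p = 2.26e-06, and adjusted p = 0.577 with an estimated correlation). 24 of 25 members were higher, with a median change of 0.23. Tcof1 (0.38, 0.25 without 2646), Pa2g4 (0.26), Fbl (0.29, 0.19 without 2567) and Nop16 (0.31) led the list by p. Treated cells' nucleotide and one-carbon synthesis genes rose (camera adjusted p = 0.000117, and adjusted p = 0.577 with an estimated correlation). 18 of 18 members were higher, with a median change of 0.20. Mthfd1l (0.35, 0.19 without 2567), Gart (0.26, 0.17 without 2646), Gmps (0.39, 0.19 without 2646) and Adsl (0.27, 0.18 and 0.44 without 2567 and 2676) led the list by p. Treated cells' TCA cycle and respiratory chain genes rose (camera adjusted p = 0.00281, lost without 2567, and adjusted p = 0.577 with an estimated correlation). 14 of 18 members were higher, with a median change of 0.15 (0.0692 without 2567). Idh3a (0.45), Cs (0.45, 0.29 without 2567), Mdh2 (0.23) and Atp5a1 (0.17) led the list by p, and 0 members passed over all genes and 2 adjusted over the list alone. Likewise, ATF4 and amino acid response genes rose (camera adjusted p = 0.000331, lost without 2646, and adjusted p = 0.577 with an estimated correlation). 16 of 18 members were higher, with a median change of 0.24 (0.12 and 0.40 without 2646 and 2676). Nars (0.66), Psph (0.62), Slc3a2 (0.45) and Slc7a5 (0.64) led the list by p, and 0 members passed over all genes and 4 adjusted over the list alone. Compared with the clones, FOXO target genes fell (camera adjusted p = 0.000105, and adjusted p = 0.577 with an estimated correlation). 14 of 16 members were lower, with a median change of -0.43 (-0.27 without 2567). Ccng2 (-1.14), Rag2 (-1.79), Ccr7 (-0.76, -0.30 and -1.21 without 2567 and 2676) and Gadd45a (-0.60, -0.99 and -0.37 without 2567 and 2646) led the list by p. Compared with the clones, mature follicular B cell genes fell (camera adjusted p = 0.00548, lost without 2567 and with no filter, and adjusted p = 0.577 with an estimated correlation). 6 of 8 members were lower, with a median change of -0.44 (-0.24 without 2567, -0.18 with no filter). Pax5 (-0.48), Ccr7 (-0.76, -0.30 and -1.21 without 2567 and 2676), Cd22 (-0.47, -0.25 without 2567) and Cd55 (-1.39, -0.19 without 2567) led the list by p, and 0 members passed over all genes and 1 adjusted over the list alone. Compared with the clones, cholesterol synthesis genes fell (camera adjusted p = 0.0135, lost without 2567 and with array weights, and adjusted p = 0.868 with an estimated correlation). 15 of 20 members were lower, with a median change of -0.16 (-0.00672 without 2567, -0.0911 with array weights). Fdft1 (-0.64, -0.36 without 2567), Insig1 (-0.51), Mvd (-0.43, -0.18 and -0.75 without 2567 and 2646) and Dhcr7 (0.25, 0.12 without 2646) led the list by p. Against the clones, 0 members of the lists given with no such count passed over all genes or adjusted over the list alone. Against the clones, tumour 2646 had medians opposite to the fitted ones, at 0.0484 for cholesterol synthesis genes. Against the clones, tumour 2676 had medians opposite to the fitted ones, at -0.0158 for ATF4 and amino acid response genes. Without the tumours in turn 5, 7 and 7 lists passed.

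Whether CHIR99021, or the state of the clones, turns back the changes of BCR loss was examined over all genes, which are not independent replicates. The loss and treatment changes correlated at -0.313 across genes, and 62.6% of genes had opposite signs. Both comparisons use the untreated BCR-negative arrays, and 100 simulations of unchanged groups gave -0.501 and 66.6%. The covariance was -0.0133, against -0.012 simulated. Between the loss change in 1 tumour and the treatment change in another, which share no array, it was -0.00651 ± 0.00879 (SD over 6 ordered pairs of tumours), within 1 SD of 0. Without tumour 2567, 2646 or 2676 it was -0.0151, -0.00501 and 0.000577. For BCR loss and BCR-independent against BCR-negative cells the correlation was -0.0765, simulated -0.502, with a covariance of -0.00246, simulated -0.012. There the covariance across tumours was 0.00413 ± 0.0115, and without those tumours in turn -0.00441, 0.00294 and 0.0139. Ighv1-72, the 1 gene called at BCR loss, kept its sign in both, and so 0 called genes were opposite. The clones' and the treatment's distances from BCR-negative cells correlated at 0.476, simulated 0.501, with a covariance of 0.0249, simulated 0.012, and 0.0133 ± 0.0221 across tumours.

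GSK3 has a known part in Wnt signalling, and the Wnt and beta-catenin target list passed in none of the 6 comparisons by camera, with a median of -0.0116 under CHIR99021 (adjusted p = 0.823). Axin2, a feedback target of that pathway, read 3.59 ± 0.0939 in untreated and 3.66 ± 0.12 in treated BCR-negative cells (SD, n = 3), near the arrays' median signal. The probe set of the mouse gene Myc, near background, read 3.32 and 3.15. Cd79a and Cd79b, the signalling chains of the receptor, read 10.03 and 9.49 in BCR-positive cells and 10.09 and 9.51 in untreated BCR-negative cells. Gsk3b read 6.94 and 6.91 in untreated and treated BCR-negative cells, and Nras 7.30 and 7.50. Ighm read between 3.51 and 4.20 on the 12 arrays. None of these 7 genes passed in any comparison by limma, the smallest adjusted p being 0.154 for Cd79b under CHIR99021. Lists of T cell, NK cell, myeloid and fibroblast markers passed in none of the 6 comparisons.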

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

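The tests for tumour 2567 and for the number of genes under CHIR99021, the title mark included, were chosen after those results were seen, and the test for opposite signs was chosen before. Of probe sets with no gene or several genes in the annotation, left out above, limma called 1 lower in BCR-independent than in BCR-negative cells. It called 4 lower in BCR-independent and 7 lower in treated BCR-negative than in BCR-positive cells.

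The 8 lists past camera at BCR loss moved less in tumour 2567, by a mean of 0.0255 in the direction of the fit against 0.289 in the other tumours. BCR-positive cells left in the sorted BCR-negative cells would bring a like share of every difference, and the Ighv1-72 signal of 15.8% there, after subtraction of the BCR-independent level from both sides, predicts a mean of 0.243. The observed shifts lay below that by a mean of 0.218 (SD 0.125 over lists, 7 of 8 below), and by 0.212 (SD 0.123) with the 18% found without subtraction, which argues against it as the whole cause. Scaling of its arrays stays open, because quantile normalization moved the median of all genes by at most 0.0273 and so hardly tested it, and the ratio of shifts went from 0.0881 to 0.177. A difference between tumours or chance in a single pair of arrays per tumour stays open and untested. So does the title mark (2), on both arrays of tumours 2646 and 2676 but not of 2567.

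Many more genes were called under CHIR99021 (248) than at BCR loss (1). The 248 genes' signed median was 0.662 ± 0.0852 against BCR-negative and 0.567 ± 0.0624 against BCR-positive arrays (SD, n = 3), a mean ratio of 0.86 (SD 0.0959). The ratio lay above the 0.507 ± 0.0344 (SD) of 100 simulations with no change, which treat genes as independent, and treated against BCR-positive cells, a difference that leaves the untreated BCR-negative arrays out, gave 104 genes (4 to 19 without each tumour, 0 with only those 2 groups in the fit), so chance confined to those BCR-negative arrays is argued against as the whole cause. Chance in the treated arrays or common to both untreated groups was not excluded, nor was the unexplained title mark, which sets untreated from treated arrays in tumours 2646 and 2676: with it as a term 32 genes were called (14 of the 248) and the mark itself called 7, while the median SE rose from 0.117 to 0.155. A difference between any 2 separately grown cultures, or one particular to the treated cultures, stays open beside an effect of the inhibitor: BCR-independent and BCR-negative cells, sorted from different mixed cultures, differed in 1 gene, but the ranges without 1 tumour, 0 to 3 there and 1 to 17 under CHIR99021, overlapped.

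Changes at BCR loss and under CHIR99021 were opposite in sign for 62.6% of genes, with 66.6% in the simulation of unchanged groups that share the untreated BCR-negative arrays. The covariance of -0.0133 was close to the simulated -0.012. Between different tumours, which share no array, it was below 0 for 4 of 6 ordered pairs, with a mean of -0.00651 ± 0.00879 (SD), and it was -0.0151, -0.00501 and 0.000577 without tumour 2567, 2646 or 2676. The shared arrays may account for the opposite signs, and a reversal of the loss by the inhibitor was neither shown nor excluded.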

How the results depend on the processing

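All alternatives but the title mark, chosen after the data were seen, were planned, and numbers in parentheses are those of the fit as reported. Without the tumour block, limma called 0 genes for BCR-negative against BCR-positive cells (against 1), 0 genes for BCR-independent against BCR-negative cells (against 1), 12 genes for treated against untreated BCR-negative cells (against 248), 4 genes for BCR-independent against BCR-positive cells (against 11), 7 genes for treated BCR-negative against BCR-positive cells (against 104) and 5 genes for treated BCR-negative against BCR-independent cells (against 21). With array weights, limma called 1635 genes for treated against untreated BCR-negative cells (against 248), 3 genes for BCR-independent against BCR-positive cells (against 11), 168 genes for treated BCR-negative against BCR-positive cells (against 104) and 39 genes for treated BCR-negative against BCR-independent cells (against 21). After cyclic loess, limma called 183 genes for treated BCR-negative against BCR-positive cells (against 104) and 37 genes for treated BCR-negative against BCR-independent cells (against 21). After quantile normalization, limma called 33 genes for treated BCR-negative against BCR-independent cells (against 21). With only the 2 groups in the fit, limma called 2 genes for BCR-negative against BCR-positive cells (against 1), 0 genes for BCR-independent against BCR-negative cells (against 1), 109 genes for treated against untreated BCR-negative cells (against 248), 1 genes for BCR-independent against BCR-positive cells (against 11), 0 genes for treated BCR-negative against BCR-positive cells (against 104) and 1 genes for treated BCR-negative against BCR-independent cells (against 21). With a 1.5-fold threshold added, limma called 163 genes for treated against untreated BCR-negative cells (against 248). With the title mark as a term, limma called 2 genes for BCR-negative against BCR-positive cells (against 1), 0 genes for BCR-independent against BCR-negative cells (against 1), 32 genes for treated against untreated BCR-negative cells (against 248), 8 genes for treated BCR-negative against BCR-positive cells (against 104) and 33 genes for treated BCR-negative against BCR-independent cells (against 21). The fewer genes without the block follow from tumour differences entering the spread, and those with the fold threshold from its construction. With the title mark the median SE was larger (0.155 against 0.117 under CHIR99021), and how much of the fall that accounts for was not tested. For 2 groups or a tumour left out (fewer arrays), array weights and the normalizations the cause was not tested. The genes called under CHIR99021 were 104 higher and 132 lower after cyclic loess and 107 and 115 after quantile normalization, against 138 and 110 as deposited. Those of treated BCR-negative against BCR-positive cells were 59 higher and 124 lower after cyclic loess, against 46 and 58. Leaving out each tumour in turn gave 0 genes for BCR-negative against BCR-positive cells, 0 to 3 genes for BCR-independent against BCR-negative cells, 1 to 17 genes for treated against untreated BCR-negative cells, 1 to 4 genes for BCR-independent against BCR-positive cells, 4 to 19 genes for treated BCR-negative against BCR-positive cells and 0 to 12 genes for treated BCR-negative against BCR-independent cells.

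Lists passing camera numbered 3 to 8 for BCR-negative against BCR-positive cells, 1 to 13 for BCR-independent against BCR-negative cells, 7 to 14 for treated against untreated BCR-negative cells, 3 to 7 for BCR-independent against BCR-positive cells, 8 to 12 for treated BCR-negative against BCR-positive cells and 5 to 7 for treated BCR-negative against BCR-independent cells without each tumour. With an estimated correlation 0 lists passed in each of the 6 comparisons. Numbers with the title mark as a term were 3 for BCR-independent against BCR-negative cells (against 9), 3 for BCR-independent against BCR-positive cells (against 5) and 6 for treated BCR-negative against BCR-positive cells (against 12). For treated against untreated BCR-negative cells it was 10 again, but 6 of them were those reported. The other alternatives left every number of lists within 1.5 times, yet ended 14 calls of named lists, 4 without the tumour block, 2 with no filter, 3 with the stricter filter, 2 after quantile normalization, 1 with array weights, 1 with only the 2 groups and 1 with mean probe sets, each given beside its list. Over all alternatives, the lists named kept their side of the threshold in 581 of 714 cases and lost the call in 124, and in 9 camera's direction turned and the call was lost, all with the title mark as a term. The medians there were 0.0339 for MYC target and ribosome biogenesis genes, 0.27 for hypoxia response genes, -0.0535 for cholesterol synthesis genes and 0.14 for mitosis genes in BCR-independent against BCR-negative cells, 0.31 for hypoxia response genes in treated against untreated BCR-negative cells, 0.24 for hypoxia response genes and 0.0605 for mitosis genes in BCR-independent against BCR-positive cells and 0.23 for hypoxia response genes and 0.21 for MHC class II and costimulation genes in treated BCR-negative against BCR-positive cells, and that of the MYC list stayed above 0 while camera's direction turned. The cause was not tested. The median of 36 of 51 named lists, and 118 of the 292 changes of named genes, 0 of them among the 60 called, moved by over 1.5 times or turned sign without 1 tumour. The fold threshold gives no value for the lists and the correlations, and the covariance between tumours has none under changes of block, trend, weights, groups or threshold. Without each tumour, the covariance between tumours lay between -0.0151 and 0.000577 for BCR loss and CHIR99021, and between -0.00441 and 0.0139 for BCR loss and BCR-independent against BCR-negative cells, so that its sign turned in both. The correlation of BCR loss with BCR-independent against BCR-negative cells was -0.0765 and lay between -0.198 and -0.0619 without each tumour.

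Named genes kept their side of the threshold in 3672 of 4071 cases, lost the call in 301 and gained it in 55. Of 60 calls of named genes, 43 were lost without the tumour block, 41 with 2 groups, 38 with the title mark as a term, and 51, 54 and 43 without tumour 2567, 2646 and 2676. The sign turned in 43 cases, all of uncalled genes. The 14 with the title mark as a term lean on tumour 2567 as the turned lists do, and for the others the cause was not tested. With array weights, turned values were Ighm (0.00454) for BCR-independent against BCR-negative cells and Cd79a (-0.0561) for treated against untreated BCR-negative cells. After cyclic loess, turned values were Axin2 (-0.0117) for BCR-independent against BCR-negative cells and Ighm (-0.0184) for treated against untreated BCR-negative cells. After quantile normalization, turned values were Cd79b (-0.0119) for BCR-negative against BCR-positive cells, Axin2 (-0.0138) for BCR-independent against BCR-negative cells, Ighm (-0.0241) for treated against untreated BCR-negative cells and Cd79b (-0.00344) for BCR-independent against BCR-positive cells. For BCR-independent against BCR-negative cells, with the title mark as a term, turned values were Cdkn1b (0.0648), Ankrd37 (0.63), Mki67 (0.0871), Cenpe (0.0351), Gsk3b (0.31) and Axin2 (-0.0241). For treated against untreated BCR-negative cells, with the title mark as a term, turned values were Ighm (-0.0939) and Gsk3b (0.29). For BCR-independent against BCR-positive cells, with the title mark as a term, turned values were Ankrd37 (0.47), Mki67 (0.045) and Gsk3b (0.25). For treated BCR-negative against BCR-positive cells, with the title mark as a term, turned values were Cenpf (0.0343), Ciita (0.0139) and Gsk3b (0.23). With the mean of a gene's probe sets, turned values were Ighm (0.031) for BCR-independent against BCR-negative cells. For BCR-negative against BCR-positive cells, leaving out each tumour, Cd79a lay between -0.13 and 0.19 and Cd79b lay between -0.11 and 0.0931. For BCR-independent against BCR-negative cells, leaving out each tumour, Ighm lay between -0.12 and 0.0318 and Gsk3b lay between -0.20 and 0.0884. For treated against untreated BCR-negative cells, leaving out each tumour, Ighm lay between -0.0861 and 0.13, Cd79a lay between -0.16 and 0.17 and Gsk3b lay between -0.18 and 0.11. For BCR-independent against BCR-positive cells, leaving out each tumour, Cd79b lay between -0.10 and 0.12, Gsk3b lay between -0.23 and 0.0723 and Nras lay between -0.033 and 0.28. For treated BCR-negative against BCR-positive cells, leaving out each tumour, Cd79a lay between -0.0214 and 0.29 and Myc lay between -0.21 and 0.00362. For treated BCR-negative against BCR-independent cells, leaving out each tumour, Ighm lay between -0.0637 and 0.11, Gsk3b lay between -0.10 and 0.0241 and Nras lay between -0.16 and 0.064. Cyclic loess moved the median of all genes by at most 0.0266 and quantile normalization by at most 0.0273 log2 units. Signals near the array medians, as of Axin2, Ciita, Ighm and Myc, limit what can be read of those genes.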

Other observations

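Over 8 pathway lists, camera found no shift past the threshold in any of the 6 comparisons, and for each list the comparison with its smallest adjusted p is given. The early activation list had a median of 0.0886 in BCR-negative against BCR-positive cells (camera adjusted p = 0.0983). The RAS ERK output list had 0.12 there (camera adjusted p = 0.485). The Wnt beta catenin target list had 0.0408 there (camera adjusted p = 0.525). The glycolysis list had a median of -0.0417 in BCR-independent against BCR-negative cells (camera adjusted p = 0.279). The germinal centre B cell list had -0.13 there (camera adjusted p = 0.18). The BCL2 family list had a median of 0.0095 in BCR-negative against BCR-positive cells (camera adjusted p = 0.609). The plasma cell list had 0.0428 there (camera adjusted p = 0.677). The interferon response list had a median of 0.19 in treated BCR-negative against BCR-positive cells (camera adjusted p = 0.145). Lists of markers of other cells had smallest camera adjusted p values over the comparisons of T cell (adjusted p = 0.535), NK cell (adjusted p = 0.343), myeloid cell (adjusted p = 0.366) and fibroblast (adjusted p = 0.367). The erythroid list had 1 tested member, Epor, and was not tested. Itgam, a myeloid marker, reached 5.97 log2 units on its highest array.

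Ighv1-72 signal on the linear scale in untreated BCR-negative cells was 18%, 8.23% and 9.01% of that in BCR-positive cells of tumours 2567, 2646 and 2676, a mean of 11.7% ± 5.43 (SD, n = 3). After the signal of BCR-independent cells of the same tumour was subtracted from both, it was 15.8%, 5.73% and 7.8%, a mean of 9.78% ± 5.32. In treated BCR-negative cells it was 10%, 4.35% and 7.61%, a mean of 7.32% ± 2.84. After that subtraction it was 7.59%, 1.75% and 6.38%, a mean of 5.24% ± 3.08. The changes between BCR-independent and BCR-positive cells and those under CHIR99021 share no array. In tumours 2646 and 2676 both set arrays without the title mark against arrays with it, which could align them. The changes correlated at 0.178 across genes, with a covariance of 0.0116 and 43.1% of signs opposite (simulated -6.5e-05, -5.79e-07 and 50%). Of the 11 genes called in the former, 7 had the same sign under CHIR99021 and 4 the opposite. Between different tumours the covariance was 0.00674 ± 0.0169 (SD over 6 ordered pairs), within 1 SD of 0.

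The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, of which 4, the real one included, part all 3 tumour pairs, and 10 splits are too few for a share under 0.05. Genes called in the real split, in the highest other split and in the highest other split that parts all pairs numbered 1, 13 and 0 for BCR-negative against BCR-positive cells, 1, 0 and 0 for BCR-independent against BCR-negative cells, 248, 0 and 0 for treated against untreated BCR-negative cells, 11, 1 and 1 for BCR-independent against BCR-positive cells, 104, 0 and 0 for treated BCR-negative against BCR-positive cells and 21, 2 and 0 for treated BCR-negative against BCR-independent cells. The split calling 13 genes at BCR loss points to a structure of the samples whose cause was not tested, and the 5 other splits there that do not part all pairs called 0 genes. Lists passing camera numbered, in the same order, 8, 9 and 7 for BCR-negative against BCR-positive cells, 9, 11 and 11 for BCR-independent against BCR-negative cells, 10, 12 and 11 for treated against untreated BCR-negative cells, 5, 11 and 6 for BCR-independent against BCR-positive cells, 12, 11 and 11 for treated BCR-negative against BCR-positive cells and 7, 9 and 6 for treated BCR-negative against BCR-independent cells. The highest other split gave more lists than the real one in 5 of the 6 comparisons.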
